A study of Arabidopsis thaliana with 6 samples.

How the data were processed

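Total RNA was extracted with TRIzol from whole Col-0 seedlings grown for 10 days without or with 5 µg/mL doxycycline, and libraries were made with the VAHTS Universal V6 RNA-seq kit, per the labels' protocols. There were 3 control and 3 doxycycline libraries, numbered 1 to 3 in each group by the labels. How messenger RNA was selected, whether strand was kept, and how reads were filtered are not given in the sources used here.

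The authors deposited 1 table of FPKM values (fragments mapped to a gene, scaled by transcript length and by the mapped total of the library), with 1 column per library and 33532 gene identifiers. Per the submitters' processing notes, TopHat2 2.1.0 and Cufflinks 2.2.1 were used with the TAIR10 genome, with no role or order given. The file's header names no unit. The unit was read from the values: the columns held decimals and did not sum to a fixed total, and the smallest values above 0 fell with gene length. FPKM divides by transcript length and by the library's total, so a change in a few abundant genes moves all others, and an exact 0 can stand for a failed estimate. Without knowledge of strand handling, reads of overlapping or antisense genes cannot be told apart, and reads shared by near-identical copies may have been split or dropped.

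Depth was estimated from the FPKM that 1 fragment is worth, using low values of genes with a single annotated transcript model of at least 600 bases. On the scale chosen for each library, a part of those low values were whole reads within 0.08 reads, where chance gives 16%. The share was 51.0% in control 1, 61.9% and 62.0% in controls 2 and 3, and 51.5%, 54.0% and 52.9% in doxycycline libraries 1 to 3. Since this is far from all values, no count model was run, and the estimates of 18500000 to 21900000 fragments describe depth only.

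Gene symbols and products were taken from a RefSeq annotation of assembly TAIR10.1, in which 32789 of the 33532 identifiers were found. It does not pair the 146 mitochondrial and 133 plastid identifiers used in the table, which are given as deposited, apart from symbols fixed in the gene lists. Because that assembly is not the one named by the submitters, its coordinates are not printed, and it served only for names, model lengths and the order of neighbouring genes.

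Values were analysed as log2(FPKM + 1), for genes with a mean of at least 1 FPKM over the 6 libraries. A fold change on this scale understates the change of low genes. Doxycycline was compared with control with limma 3.58.1 in R 4.3.3, using moderated variances with a trend on abundance and no covariate, two-sided, with Benjamini-Hochberg adjustment over 19035 genes and a threshold of 0.05. A further count took genes at 2-fold or more. Gene lists with at least 5 measured members were tested with limma's camera with a preset correlation between genes of 0.01, and Benjamini-Hochberg adjustment over 33 lists. Camera compares a list with all other genes, so its direction can differ from the sign of the list's median. It was repeated with an estimated correlation, and fry, which tests whether a list's genes move one way on balance, was run beside it.

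There were 35 lists: 30 of named members covering mitochondrial stress, respiration, plastid function, hormones, defence compounds, nutrient responses, stress, cell cycle and markers of organs and cell types, and 5 by rule, namely genes of the mitochondrial and of the plastid genome and nuclear genes of mitochondrial, plastid and cytosolic ribosomal proteins as the reference names them. Members came from general knowledge of the pathways and were checked against the reference's symbols. Lists, tests, the settings to compare and the rule for naming genes were fixed before the data were examined. The rule took up to 6 genes in each direction past the threshold with no overlap between groups (0 passed), AOX1A, the 4 members with the lowest adjusted p in each of the 8 lists with the lowest camera p, and the member with the lowest adjusted p in every other list. A few other genes are named as examples, such as LOX3 and UPOX, chosen after their values were seen.

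After the data were seen, a further measure was added: the log2 distance between the closest control and doxycycline libraries of a gene whose groups do not overlap, counted from 1 (2-fold). The 12 genes farthest apart in each direction were named where space allowed. Differences of the mean of the doxycycline libraries from each control library were also given, since the controls differed from each other. A list's median against control 1 was set among 10000 random lists of the same size matched on mean expression in 20 bins.

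Alternatives were pseudocounts of 0.1 and 0.01, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, robust variance estimates, a block for the replicate number, each library left out in turn, and, added later, control 1 as the only control. Count-based tests chosen in case the table held counts were not run, as the table holds no counts. All 10 splits of the 6 libraries into groups of 3 were compared.

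The tests were tried on simulated values for the 19035 genes of the doxycycline against control comparison, with 50 genes changed at each size. With the spread seen between doxycycline libraries in both groups, limma recovered 74%, 92%, 100% and 100% of genes changed by 1, 2, 3 and 4 log2 units, with 10 false calls. With each group's own spread it recovered 22%, 66%, 94% and 94%, with 38 false calls, and the separation measure of 2-fold found 8%, 76%, 100% and 98%, with 47 false genes (1 at equal spread). Of unchanged genes, 15.8% did not overlap between groups with each group's own spread and 10.1% at equal spread. The simulated spread was independent between genes, unlike the spread between these controls, so these rates are only rough guides to the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.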

Results

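RNA sequencing was carried out on whole wild-type Arabidopsis thaliana seedlings of the Col-0 accession, the common laboratory strain. Seedlings grew for 10 days on half-strength Murashige and Skoog medium (written 1/2 MS in the labels) with or without 5 µg/mL doxycycline, a tetracycline antibiotic that blocks bacterial-type ribosomes, such as those of mitochondria and plastids. The design text describes the 3 libraries of each condition as biological replicates. It does not say whether plates or harvests were separate, so the p-values given here measure the spread between these 6 libraries. Expression values were FPKM for 33532 gene identifiers, of which 19035 had a mean of at least 1 FPKM and were tested. The size of the smallest values put the depth at an estimated 19200000, 18500000 and 21900000 fragments for controls 1 to 3 and 20600000, 20700000 and 20800000 for doxycycline libraries 1 to 3.

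The 3 doxycycline libraries resembled each other closely, with Pearson correlations of log2 values across genes of 0.988 to 0.992, while the 3 controls did not, at 0.831 to 0.895. Control 1 lay nearer to the doxycycline libraries (0.961 to 0.964) than to the other controls, and controls 2 and 3 correlated with the doxycycline libraries at 0.827 to 0.856. Genes are not independent replicates in these correlations. The median standard deviation of a gene on the log2 scale was 0.459 between controls and 0.131 between doxycycline libraries. A gene annotated for 18S ribosomal RNA (AT3G41768) stood at 954, 10573 and 457 FPKM in controls 1 to 3 and at 1833, 1374 and 1356 FPKM in the doxycycline libraries.

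**Figure D1:**
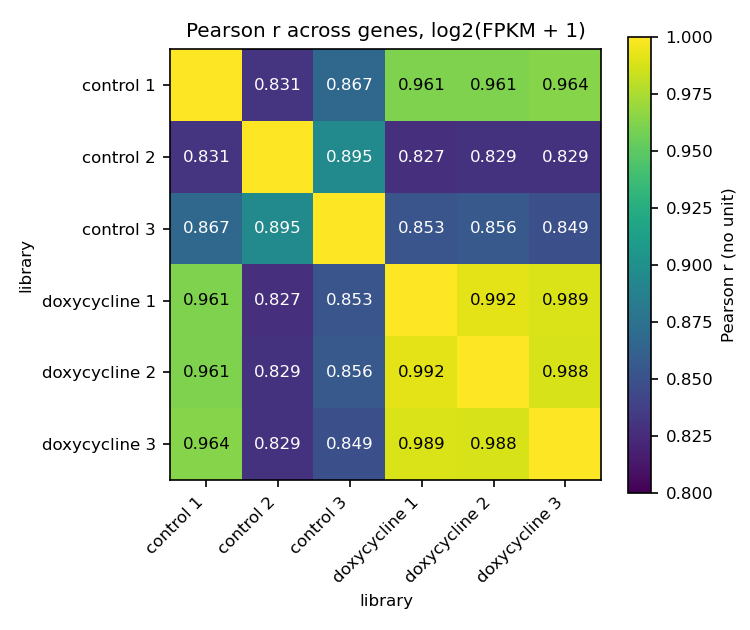
Pearson correlation across 19035 genes of log2(FPKM + 1) for each pair of the 6 libraries, with libraries on both axes, values printed in the cells and no unit. The 3 doxycycline libraries correlated at 0.988 to 0.992, control 1 with them at 0.961 to 0.964, and controls 2 and 3 with them at 0.827 to 0.856.

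The series title gives the question as the response of the seedling transcriptome when mitochondrial translation is impaired. In the doxycycline libraries, most transcripts in the lists of jasmonate-inducible genes, glucosinolate synthesis and the phosphate starvation response lay below every control library. VSP2 (AT5G24770), which encodes a vegetative storage protein, stood at 11.3 ± 2.51 FPKM (SD, n = 3) with doxycycline and at 83.2, 293 and 863 FPKM in controls 1 to 3. The sulfotransferase gene SOT18 (AT1G74090), for the last step of glucosinolate core synthesis, stood at 9.66 ± 1.27 FPKM with doxycycline and 33.1 ± 8.74 FPKM in controls (SD, n = 3 each). On the higher side was SAG21 (AT4G02380), at 787 ± 105 against 171 ± 41.2 FPKM. So was the magnesium chelatase gene CHLI2 (AT5G45930) of chlorophyll synthesis, at 70.7 ± 9.88 against 15.2 ± 7.77 FPKM. The plastid identifier ATCG00450, for which the reference gave no product, stood at 56.9 ± 2.51 against 14.9 ± 2.73 FPKM. Transcripts of AOX1A (AT3G22370), the alternative oxidase gene commonly used as a marker of mitochondrial dysfunction, did not separate the groups.

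With limma on log2(FPKM + 1), 0 of 19035 genes passed a Benjamini-Hochberg adjusted p of 0.05, hence 0 at 2-fold or more, and the lowest adjusted p was 0.121. At an unadjusted p under 0.05 there were 4876 genes, 1301 higher and 3575 lower with doxycycline, where chance alone gives about 952. Limma with robust variance estimates also called 0 genes. In 6714 genes (35.3%, where chance gives 10% at equal spread and simulated unchanged genes with each group's own spread gave 15.8%) the groups did not overlap, 1825 with higher and 4889 with lower doxycycline values. In 121 of these the closest control and doxycycline libraries still differed by at least 2-fold on the log2(FPKM + 1) scale, 34 higher and 87 lower, where the simulation with each group's own spread gave 47 unchanged genes. That measure was chosen after the data were seen. The simulated spread was independent between genes, unlike that between these controls, so 15.8% and 47 are only rough guides. After median-of-ratios scaling the 2-fold separated genes were 48 higher and 60 lower, and after quantile normalization 46 higher and 54 lower. The median gene lay at -0.29 log2 with doxycycline on the deposited scale, against -0.01 and 0.01 under those scalings.

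The count of changed genes depended on control 1. Without it, limma called 8637 genes, 1860 higher and 6777 lower, of which 4786 at 2-fold or more, and 2448 genes were separated at least 2-fold. Leaving out control 3 gave 2 genes, the near-identical plant defensin genes PDF1.2A and PDF1.2b, and leaving out any other single library gave 0. The 2-fold separated count was 200 without control 2 and 197 without doxycycline library 3. With control 1 as the only control, a choice made after seeing the data in which the lone library is assumed to vary like the doxycycline libraries, limma called 2194 genes, 1290 higher and 904 lower, of which 682 at 2-fold or more. The mean of the doxycycline libraries lay at least 2-fold from control 1 in 818 genes, from control 2 in 6628 and from control 3 in 4665.

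**Figure D2:**
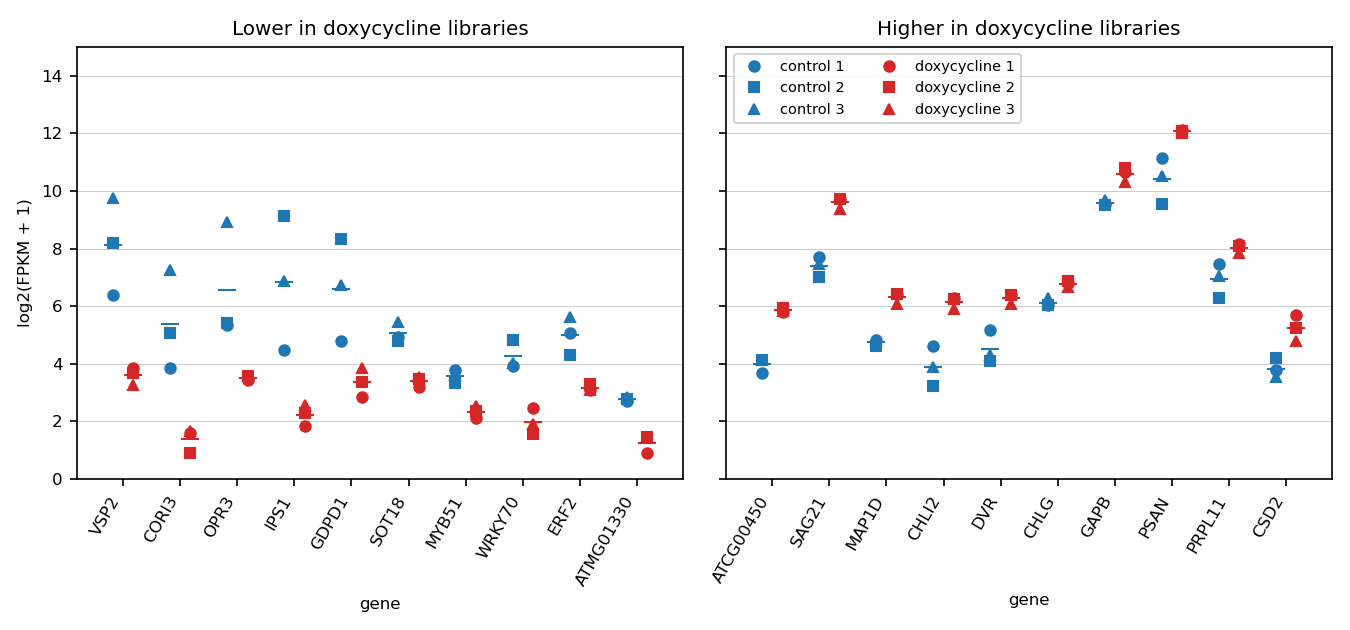
Expression of 20 named genes in each library, as log2(FPKM + 1) on the vertical axis, with genes that were lower with doxycycline on the left and higher on the right. Blue points are controls, red points doxycycline libraries, marker shape gives the replicate number, and short bars are group means of the log2 values. VSP2 stood at 83.2 to 863 FPKM in controls and 8.65 to 13.6 FPKM with doxycycline, and SAG21 at 127 to 209 and 667 to 852 FPKM.

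Jasmonate genes, fixed as a list of 20 before the data were examined, were shifted downward (camera, adjusted p = 9.56e-05; adjusted p = 0.676 with an estimated correlation). In 15 of the 20 every doxycycline library lay below every control, in 8 by at least 2-fold, and 0 lay above. None passed over all genes and 7 were lower past the threshold when adjusted over the list alone. Here and below, that adjustment leaves out all other genes and lists. With limma, 4876 of the 19035 genes had an unadjusted p under 0.05, and genes of one list vary together. Such counts are therefore descriptive. The list's median log2 difference was -1.11 against control 1, -1.93 against control 2 and -5.23 against control 3, where the medians of all genes were -0.00, -0.54 and -0.30. Against control 1 alone the list stayed shifted downward (camera, adjusted p = 1.31e-10; adjusted p = 0.509 with an estimated correlation), with 13 genes lower and 0 higher past the threshold over all genes. CORI3 (AT4G23600), induced by jasmonate and coronatine, stood at 13.5, 32.7 and 151 FPKM in controls 1 to 3 and 2.06, 0.856 and 2.17 FPKM with doxycycline, a log2 difference of -4.00 (SE 0.788, adjusted p = 0.121). VSP1 (AT5G24780) gave -4.04 (SE 0.935, adjusted p = 0.128), and OPR3 (AT2G06050), a jasmonate synthesis enzyme, -3.05 (SE 0.902, adjusted p = 0.140), with 39.8, 41.9 and 487 FPKM in the controls against 10.5 ± 0.612 FPKM (SD, n = 3). Control 3 held most of the jasmonate transcripts, with the synthesis gene LOX3 at 193 FPKM against 3.28 and 2.75 FPKM in controls 1 and 2. The ethylene- and jasmonate-responsive defensin gene PDF1.2A (AT5G44420) stood at 108, 62.3 and 2.48 FPKM in the controls and was listed at 0 in all 3 doxycycline libraries, as was PDF1.2b (AT2G26020) against 28.1, 19.8 and 3.3 FPKM. VSP1 and VSP2, and PDF1.2A and PDF1.2b, are near-identical copies, so the split of reads within each pair is uncertain.

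Other defence lists shifted the same way. Of 17 ethylene genes 9 lay below every control and 0 above, with 6 lower when adjusted over the list alone (camera, adjusted p = 0.00414; adjusted p = 0.676 with an estimated correlation). This was the 1 list that passed with fry, at an adjusted p of 0.0235. Fry does not set a list against other genes, so the lower median of all genes (-0.29) counts toward a downward call. It was run on the deposited scale only. The ethylene response factor gene ERF2 (AT5G47220) stood at 7.99 ± 0.831 FPKM with doxycycline and 33.4 ± 15 FPKM in controls (SD, n = 3 each; log2 difference -1.84, SE 0.334, adjusted p = 0.121). Of 11 salicylate genes 7 lay below every control and 0 above, with 1 lower over the list alone (camera, adjusted p = 0.0328; adjusted p = 0.676 with an estimated correlation). That gene was WRKY70 (AT3G56400), a transcription factor of the salicylate and jasmonate pathways, at 3.08 ± 1.33 against 19.1 ± 7.49 FPKM (SD, n = 3 each; log2 difference -2.29, SE 0.346, adjusted p = 0.121). Medians against controls 1 to 3 were -0.71, -1.18 and -0.50 for ethylene and -0.39, -1.26 and -1.08 for salicylate.

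Genes of glucosinolate synthesis, the sulfur-rich defence compounds of the cabbage family, were shifted downward, with medians of -1.07, -0.98 and -1.97 against controls 1 to 3 over 19 genes (camera, adjusted p = 0.00112; adjusted p = 0.676 with an estimated correlation). Of the 19, 11 lay below every control, 4 of them by at least 2-fold, and 8 were lower when adjusted over the list alone. SOT18 had a log2 difference of -1.66 (SE 0.232), the plastid transporter gene BAT5 (AT4G12030) -1.37 (SE 0.240) and MYB51 (AT1G18570), a regulator of indole glucosinolates, -1.23 (SE 0.229), each with an adjusted p of 0.121. SUR1 (AT2G20610), for the carbon-sulfur lyase of the pathway, stood at 34.6, 36.8 and 101 FPKM in controls and 14.5 ± 0.783 FPKM (SD, n = 3) with doxycycline.

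The phosphate starvation list of 14 genes had a median of -3.32 over all libraries, and of -1.04, -5.33 and -3.69 against controls 1 to 3 (camera, adjusted p = 2.98e-04; adjusted p = 0.676 with an estimated correlation). Of the 14, 10 lay below every control, 4 of them by at least 2-fold, and 10 were lower when adjusted over the list alone. The non-coding transcript IPS1 (AT3G09922) stood at 21.4, 565 and 116 FPKM in controls and 2.57, 3.86 and 4.90 FPKM with doxycycline. GDPD1 (AT3G02040), for a glycerophosphodiester phosphodiesterase, stood at 26.6, 319 and 106 FPKM against 9.69 ± 3.6 FPKM (SD, n = 3), and MGD2 (AT5G20410), for a galactolipid synthase, at 7.54, 71.1 and 25.4 against 3.04 ± 1.09 FPKM. The related transcript AT4 (AT5G03545) reached 2575 FPKM in control 2, against 130 in control 1 and 50.6 ± 9.56 FPKM with doxycycline.

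Chosen after the data were seen, Fisher's exact tests placed genes that were at least 2-fold below every control more often in these lists than among all genes tested: jasmonate (8 of 20, adjusted p = 1.15e-12), phosphate starvation (4 of 14, adjusted p = 1.38e-05), glucosinolate synthesis (4 of 19, adjusted p = 3.49e-05) and ethylene (2 of 17, adjusted p = 0.0470). These tests treat genes as independent, which genes of one pathway are not.

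Nuclear genes of photosynthesis were shifted upward as a list of 49 (camera, adjusted p = 4.06e-13; adjusted p = 0.676 with an estimated correlation). Medians were 0.01, 1.83 and 0.83 against controls 1 to 3, and with control 1 as the only control the list's adjusted p was 0.799, with 17 genes above control 1 in all doxycycline libraries and 22 below. Of the 49, 15 lay above every control and 1 below, and 0 passed when adjusted over the list alone. PSAN (AT5G64040), a photosystem I subunit gene, stood at 2274, 739 and 1475 FPKM in controls and 4311 ± 134 FPKM (SD, n = 3) with doxycycline, and the light-harvesting gene LHCB6 (AT1G15820) at 2869, 852 and 1537 against 4484 ± 253 FPKM. GAPB (AT1G42970), a Calvin cycle enzyme gene, stood at 768 ± 42.5 FPKM in controls and 1564 ± 269 FPKM with doxycycline, and PSBQA (AT4G21280) at 718 ± 251 and 1479 ± 187 FPKM (SD, n = 3 each). Several members of this list have near-identical copies, and their values are uncertain in the same way.

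Chlorophyll synthesis genes were likewise shifted upward (camera, adjusted p = 2.26e-04; adjusted p = 0.676 with an estimated correlation), with 5 of 13 above every control, 0 below and 4 higher when adjusted over the list alone. Medians were -0.01, 0.75 and 0.50 against controls 1 to 3. The list was not called with control 1 alone (adjusted p = 0.782), which 6 genes lay above and 5 below in all doxycycline libraries. The 4 genes were DVR (AT5G18660), for divinyl reductase, with a log2 difference of 1.77 (SE 0.298, adjusted p = 0.121), CHLG (AT3G51820), for chlorophyll synthase, with 0.66 (SE 0.170, adjusted p = 0.132), CHLI1 (AT4G18480) with 1.02 (SE 0.308, adjusted p = 0.142) and CHLM (AT4G25080) with 1.26 (SE 0.390, adjusted p = 0.142). DVR stood at 35.0, 16.2 and 18.6 FPKM in controls and 78.0 ± 9.49 FPKM (SD, n = 3) with doxycycline.

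Among organelle ribosomes, the 6 plastid ribosomal protein genes that the reference names as such were shifted upward (camera, adjusted p = 0.00133; adjusted p = 0.676 with an estimated correlation), 4 of them above every control and 4 higher when adjusted over the list alone. Their medians were 0.30, 1.67 and 0.99 against controls 1 to 3. PRPL11 (AT1G32990) stood at 262 ± 27.4 against 128 ± 49.8 FPKM and PRPS20 (AT3G15190) at 374 ± 24.8 against 190 ± 99.2 FPKM, and PSRP6 (AT5G17870) and PSRP4 (AT2G38140) had log2 differences of 1.00 (SE 0.347) and 1.01 (SE 0.381). The 8 mitochondrial ribosomal protein genes were not shifted (camera, adjusted p = 0.901), and their median of -0.22, with 0.26, -0.57 and -0.32 against controls 1 to 3, became 0.05 after median-of-ratios scaling. RPS14 (AT2G34520) of that list stood at 46.7 ± 3.53 against 31.2 ± 7.49 FPKM (SD, n = 3 each). MAP1D (AT4G37040), for a methionine aminopeptidase of organelles, was at least 2-fold above every control, at 79.1 ± 10.6 against 25.9 ± 2.18 FPKM.

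Genes of the mitochondrial genome were shifted downward (camera, adjusted p = 4.60e-06; adjusted p = 0.720 with an estimated correlation). Of the 42 measured, 24 lay below every control, 0 above, and 16 were lower when adjusted over the list alone. Medians were -0.28, -2.14 and -1.54 against controls 1 to 3. In 24 genes every doxycycline library lay below control 1, and in 7 every one lay above it. ATMG01220 stood at 4.21, 5.45 and 7.80 FPKM in controls and 0.421, 0 and 0.277 FPKM with doxycycline, ATMG01330 at 5.81 ± 0.320 and 1.45 ± 0.494 FPKM, ATMG01380 at 19.3 ± 5.5 and 5.52 ± 1.5 FPKM, and ATMG01090 at 8.76 ± 4.16 and 1.43 ± 0.653 FPKM (SD, n = 3 each). The reference gave no product for these identifiers. The summed FPKM of mitochondrial genes was 275, 2215 and 672 in controls 1 to 3 and 422, 291 and 443 in the doxycycline libraries. Each doxycycline sum thus lay above that of control 1 and below those of controls 2 and 3. Nuclear copies of organelle DNA, and the way organelle transcripts were selected for the libraries, leave these levels uncertain.

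Genes of the plastid genome were shifted upward relative to other genes (camera, adjusted p = 0.00414; adjusted p = 0.928 with an estimated correlation), although their median of -0.07 and mean of -0.05 were slightly negative and the median turned to 0.17 after median-of-ratios scaling. Of 95 measured, 8 lay above and 6 below every control. Adjusted over the list alone, 1 was higher, ATCG00450, for which the reference gave no product. Medians were 0.52, -1.64 and 0.71 against controls 1 to 3. The summed FPKM of plastid genes was 3677 in control 2, against 825 to 2016 in the other libraries. The 5 measured genes read mainly by the nuclear-encoded plastid RNA polymerase were shifted upward (camera, adjusted p = 0.00676; adjusted p = 0.676 with an estimated correlation), with medians of 1.03, -0.01 and 1.03 and 2 genes higher over the list alone. RPOB (ATCG00190), for a subunit of the plastid's own RNA polymerase, stood at 9.84 ± 2.16 FPKM against 4.94 ± 0.399 FPKM (SD, n = 3 each). The 7 genes read mainly by the plastid-encoded polymerase were not shifted (camera, adjusted p = 0.405), with medians of -0.55, -3.13 and 0.19, and PSAA (ATCG00350) stood at 5.52, 45.6 and 2.91 FPKM in controls and 2.75, 2.19 and 1.18 FPKM with doxycycline.

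**Figure D3:**
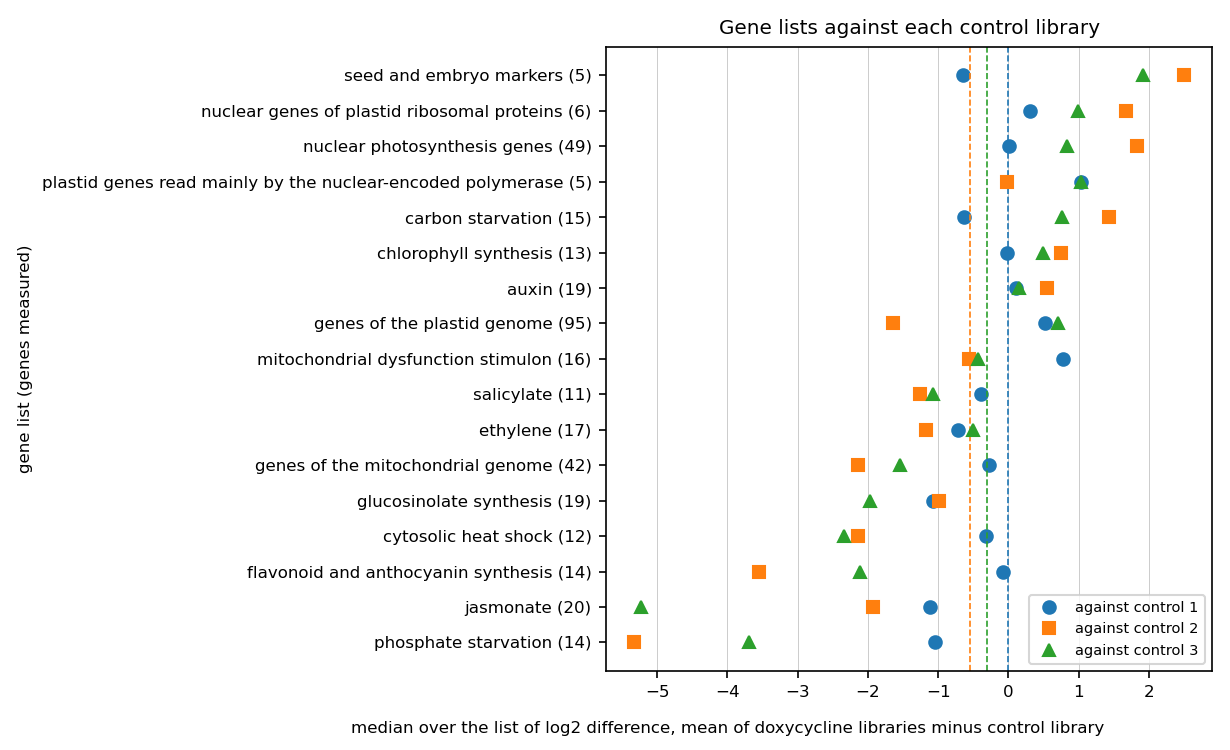
Median log2 difference of the mean of 3 doxycycline libraries from each control library (horizontal axis, log2 units) for the 16 gene lists past the camera threshold and the mitochondrial dysfunction stimulon, with the number of genes measured. Circles, squares and triangles are controls 1, 2 and 3, and dashed lines are the medians of all genes against each. Jasmonate genes lay at -1.11, -1.93 and -5.23, and photosynthesis genes at 0.01, 1.83 and 0.83.

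The lists of mitochondrial stress were not shifted over all libraries. The mitochondrial dysfunction stimulon, the set of nuclear genes known to respond when mitochondria fail, had a camera adjusted p of 0.235, and its median of -0.15 became 0.14 after median-of-ratios scaling. Its medians were 0.77, -0.56 and -0.43 against controls 1 to 3. In 14 of its 16 genes every doxycycline library lay above control 1, against 2 genes above every control. UPOX (AT2G21640), one of those 2, stood at 4.31, 40.8 and 18.6 FPKM in controls and 48.1, 45.6 and 41.9 FPKM with doxycycline. With control 1 as the only control, 7 genes of the list were higher past the threshold over all genes, and the list was shifted upward (camera, adjusted p = 2.30e-07; adjusted p = 0.509 with an estimated correlation). AOX1A stood at 23.4, 46.6 and 44.9 FPKM in controls 1 to 3 and 38.8, 42.5 and 36.7 FPKM with doxycycline, a log2 difference of 0.10 (SE 0.281, adjusted p = 0.826) that was -0.21 without control 1. Against controls 1 to 3 taken singly, the log2 difference of AOX1A was 0.72, -0.24 and -0.19, so its sign turned on which control was used. BCS1 (AT3G50930) stood at 1.69, 9.75 and 17.3 FPKM against 1.45 ± 0.317 FPKM (SD, n = 3).

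Mitochondrial chaperones and proteases (19 genes) had medians of 0.67, -1.10 and -0.69 against controls 1 to 3 and a camera adjusted p of 0.750. Against control 1 alone they were shifted upward (camera, adjusted p = 1.09e-04; adjusted p = 0.581 with an estimated correlation), with 9 genes higher past the threshold over all genes. FTSH4 (AT2G26140), an inner membrane protease gene, stood at 19.3 ± 1.97 against 37.3 ± 11.7 FPKM. Alternative respiration genes (11 measured) had medians of 0.15, -0.83 and -0.41 (adjusted p = 0.639), and the low AOX1D (AT1G32350) stood at 0.0950 ± 0.0407 against 2.17 ± 1.60 FPKM. Nuclear genes of respiratory complexes and ATP synthase (35 genes) had medians of 0.27, -0.52 and -0.34 (adjusted p = 0.806), and the list's median over all libraries was -0.27 but 0.04 after median-of-ratios scaling. Against control 1 alone this list was shifted upward as well (camera, adjusted p = 0.00261; adjusted p = 0.581 with an estimated correlation), with 8 genes higher. FRO1 (AT5G67590), a complex I subunit gene, stood at 109 ± 1.23 against 80.9 ± 0.365 FPKM (SD, n = 3 each; log2 difference 0.42, SE 0.154, adjusted p = 0.165). Detoxification genes and NAC regulators (17 measured) had a median of -0.64 (adjusted p = 0.604) with 0.33, -1.17 and -0.90 against controls 1 to 3, and passed, upward, with control 1 as the only control (camera, adjusted p = 0.0473; adjusted p = 0.639 with an estimated correlation). Antioxidant genes (14 measured) had a median of -0.73 (adjusted p = 0.980), with -0.05, -0.57 and -0.97 against controls 1 to 3. After median-of-ratios scaling and quantile normalization the medians over all libraries were -0.13 and -0.17 for chaperones and proteases (-0.43 before), -0.08 and -0.14 for alternative respiration (-0.39 before), -0.37 and -0.33 for detoxification and -0.45 and -0.64 for antioxidant genes. GSTF6 (AT1G02930), a glutathione transferase gene, stood at 11.5 ± 1.03 against 46.4 ± 26.0 FPKM, and CSD2 (AT2G28190), for the plastid copper/zinc superoxide dismutase, at 38.0 ± 12 against 13.5 ± 3.39 FPKM (SD, n = 3 each).

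The remaining lists past the camera threshold differed between controls. Carbon starvation genes (15 measured) were shifted upward (adjusted p = 3.98e-04; adjusted p = 0.676 with an estimated correlation), yet their medians of -0.63, 1.43 and 0.76 turned sign with the control, and the shift was downward against control 1 alone (adjusted p = 0.00362; adjusted p = 0.581 with an estimated correlation). DIN10 (AT5G20250) stood at 556, 42.7 and 122 FPKM in controls and 427 ± 23.2 FPKM with doxycycline, MCCB (AT4G34030) at 69.2, 24.3 and 26.4 against 67.4 ± 4.96 FPKM, BGLU30 (AT3G60140) at 0.613, 23 and 11.3 against 48.6, 46.0 and 15.5 FPKM, and TPS9 (AT1G23870) at 28.7 ± 7.86 against 37.2 ± 3.74 FPKM. Seed and embryo markers (5 measured) had medians of -0.64, 2.51 and 1.92 (shifted upward, adjusted p = 0.00287; adjusted p = 0.676 with an estimated correlation), with EM6 (AT2G40170) at 2.02, 0.611 and 0.964 FPKM against 3.86, 5.07 and 15.2 FPKM. Cytosolic heat shock genes (12 measured) had medians of -0.31, -2.14 and -2.34 (shifted downward, adjusted p = 0.00441; adjusted p = 0.676 with an estimated correlation), with HSP18.2 (AT5G59720) at 2.2 ± 0.424 against 4.81 ± 0.255 FPKM. Flavonoid and anthocyanin synthesis genes (14 measured) had medians of -0.07, -3.54 and -2.11 (shifted downward, adjusted p = 0.00441; adjusted p = 0.839 with an estimated correlation), and CHS (AT5G13930), for chalcone synthase, stood at 10.3, 181 and 122 FPKM in controls and 8.10 ± 1.87 FPKM with doxycycline. Auxin genes (19 measured) had medians of 0.11, 0.55 and 0.15 (shifted upward, adjusted p = 0.0108; adjusted p = 0.676 with an estimated correlation), while ARF19 (AT1G19220), an auxin response factor gene, went the other way at 3.58 ± 0.473 against 6.49 ± 1.5 FPKM.

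In all, camera with the preset correlation of 0.01 placed 16 of 33 lists past the threshold, 8 upward and 8 downward, and 0 with the correlation estimated from the data. After quantile normalization the calls were 4 upward and 7 downward. Median-of-ratios scaling or quantile normalization moved several medians over all libraries by more than 1.5 times without a change of sign. Among the called lists these were photosynthesis (0.89, against 1.21 and 0.38), chlorophyll synthesis (0.37, against 0.69 and 0.31), ethylene (-0.94, against -0.69 and -0.54), auxin (0.16, against 0.46 and 0.37) and salicylate (-0.87, against -0.65 and -0.48). Of the 16 lists, 11 had medians of one sign against each of the 3 controls. With control 1 as the only control 18 lists passed, 10 upward and 8 downward, and 0 with an estimated correlation (lowest adjusted p = 0.509). Seed and embryo, photosynthesis, chlorophyll, heat shock, flavonoid and auxin lists then no longer passed. Cytosolic ribosomal proteins (adjusted p = 0.00238), root markers (0.0142) and cell cycle genes (0.0191) then passed upward and plastid genes read by the plastid-encoded polymerase (0.0454) downward.

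The other lists did not pass, and their medians against controls 1 to 3 follow the adjusted p and the median over all libraries. Xylem and secondary wall markers (adjusted p = 0.1, median -0.74, with -0.04, -1.23 and -1.0) included IRX1 (AT4G18780), at 0.455 ± 0.0908 against 1.94 ± 1.03 FPKM. Guard cell markers (adjusted p = 0.119, median 0.13, with 0.27, 0.07 and -0.03) included TMM (AT1G80080), at 6.24 ± 0.112 against 3.33 ± 0.684 FPKM (SD, n = 3 each). Cytosolic ribosomal proteins (adjusted p = 0.106) had a median of -0.01 that became 0.29 after median-of-ratios scaling, with 0.32, -0.36 and 0.09 against the controls, and AT4G00810 of that list stood at 232 ± 21.1 against 152 ± 31.2 FPKM. Cell cycle genes (adjusted p = 0.312) had a median of -0.08 that became 0.16, with 0.29, -0.69 and 0.19 against the controls, and CYCA1;1 (AT1G44110) stood at 6.68 ± 0.357 against 3.87 ± 1.26 FPKM. Iron deficiency genes (adjusted p = 0.318, median -0.60, with -0.12, -0.78 and -0.76) included BTS (AT3G18290), at 10.4 ± 1.04 against 23.1 ± 8.55 FPKM, and hypoxia genes (adjusted p = 0.325, median -1.03, with 0.12, -2.91 and -0.04) included ALAAT1 (AT1G17290), at 46.1 ± 2.34 against 64.6 ± 11.1 FPKM. Abscisic acid and osmotic stress genes (adjusted p = 0.453, median -0.67, with -0.18, -0.02 and -1.13) included the cold- and drought-induced KIN1 (AT5G15960), at 4.40 ± 1.25 against 30.6 ± 23.9 FPKM. Root markers (adjusted p = 0.968) had medians of 0.38, -1.05 and -0.95 against controls 1 to 3, with THAS1 (AT5G48010) at 10.4, 59.2 and 57.0 FPKM in controls and 7.41 ± 1.06 FPKM with doxycycline. Root hair markers (adjusted p = 0.405, median -0.88, with -0.27, -0.03 and -2.18) included PRX73 (AT5G67400), at 2.70, 1.27 and 13.4 against 0.355, 0.234 and 1.56 FPKM. Most of these medians lay nearer to 0 after median-of-ratios scaling and quantile normalization, at -0.54 and -0.36 for xylem, -0.38 and -0.19 for iron deficiency, -0.79 and -0.67 for hypoxia, -0.40 and -0.31 for abscisic acid, -0.24 and -0.08 for root (-0.47 before) and -0.58 and -0.59 for root hair markers, while guard cell markers lay farther from it, at 0.40 and 0.53. Ferritin and flower lists had 4 and 2 measured genes, too few for the set test, and medians of 0.21, -0.64 and -0.11 and of 0.12, 0.40 and -0.57 (-0.32 and -0.018 over all libraries, -0.025 and 0.18 after median-of-ratios scaling, -0.058 and 0.34 after quantile normalization), with FER4 (AT2G40300) at 48.0 ± 10.0 against 37.6 ± 2.98 FPKM and SEP3 (AT1G24260) at 6.91 ± 0.692 against 3.71 ± 2.30 FPKM.

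Among genes outside the lists, AT5G42530 had the widest gap between its closest control and doxycycline libraries. It is annotated only as an uncharacterized protein and stood at 127, 861 and 468 FPKM in controls and 13.5 ± 1.90 FPKM (SD, n = 3) with doxycycline. The glutaredoxin family gene AT2G47880 stood at 1.96 ± 0.710 against 26.8 ± 14 FPKM, AT1G24145 at 1.25 ± 0.419 against 14.2 ± 4.98 FPKM and AT4G13572 at 1.52 ± 0.225 against 19.6 ± 11.3 FPKM. Higher with doxycycline were the lectin family gene AT1G52100 (42.9 ± 4.43 against 8.32 ± 3.94 FPKM), AT1G68238 (21.9 ± 2.99 against 3.25 ± 2.63 FPKM), TCL1 (AT2G30432), a repressor of trichome formation (4.78 ± 0.463 against 0.651 ± 0.422 FPKM), AT2G22122 (75.7 ± 15.9 against 13.1 ± 12.3 FPKM) and AT5G01740 (92.3 ± 11.1 against 31.4 ± 4.19 FPKM). The SAUR-like gene AT4G34810 stood at 6.05 ± 0.664 against 1.48 ± 0.424 FPKM, AT3G17520 of the late embryogenesis abundant family at 8.47, 10.0 and 21.3 against 3.04, 0.246 and 1.59 FPKM, and AT4G08093 at 3.79 ± 0.141 against 0.525 ± 0.155 FPKM (SD, n = 3 each). These genes were picked by the measure chosen after the data were seen.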

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

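The 2-fold separated count and the use of control 1 as the only control were chosen after the data were seen. Genes changed with doxycycline numbered 0 under each pseudocount, filter and scaling tried and with robust variances. Leaving out 1 library gave 0 to 8637, and 0 to 4786 at 2-fold or more. The highest counts came without control 1, the control nearest to the doxycycline libraries, and why the controls differ is taken up below. With control 1 as the only control there were 2194, and 682 at 2-fold or more. Genes separated at least 2-fold numbered 268 with a pseudocount of 0.1 and 302 with 0.01, since a smaller pseudocount widens distances of low genes. They numbered 441 with control 1 as the only control, 2448 without control 1, and 144 to 200 with any other single library left out. Fewer libraries overlap less, but that alone does not account for the 2448, since leaving out control 2 gave 200 and control 3 gave 155. Shifted gene lists numbered 11 to 17 under the other pseudocounts, filters and scalings, 13 to 18 with 1 library left out, 0 with an estimated correlation and 1 with fry. Those 2 methods allow for correlation between the genes of a list. The log2 changes of the 78 named genes kept their sign in the 612 values of the 8 settings that keep all libraries. With a mean of at least 5 FPKM only 66 of the 78 were tested. In these settings 0 genes passed the threshold, so the side of it could not change. Of the 468 values of named genes with 1 library left out, 397 kept sign and side of the threshold, 70 passed it in the same direction and 1 turned sign. The log2 change of AOX1A ranged from -0.21 (without control 1) to 0.27 with 1 library left out. It, and those of MCCB (-0.039) and DIN10 (-0.38) with control 1 as the only control, turned sign, and none was past the threshold. Replicate numbers did not pair the libraries (correlations of same-numbered deviations -0.00, -0.01 and -0.14), and the replicate block gave 0 changed genes and 16 lists. Tests for counts (edgeR, DESeq2) were not run, as the table holds no counts, and weights per library, tried after the data were seen, did not converge and gave no value. Depth was close to even and does not set apart controls 2 and 3. The share of low values that were whole reads did, at 61.9% and 62.0% in these controls against 51.0% to 54.0% in the other libraries. The cause of that difference was not tested.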

Other observations

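The tests in this part were chosen after the results were seen, except the splits of the counts of changed genes and shifted lists. For the clock gene test of controls 2 and 3 and the random-list test of the mitochondrial dysfunction list, the bounds were set before their values were seen. A test of root hair genes was dropped because their values were near 0, and the root test given here replaced it. The scaling test of the jasmonate list replaced one against control 1, where scaling had nothing to move, that of a wrong label replaced one that rested on a correlation, and that of controls 2 and 3 as the only source replaced one that rested on random lists alone. Genes of the circadian clock divided the controls. LHY, a morning-phased clock gene, stood at 1.76 FPKM in control 1, 235 and 203 FPKM in controls 2 and 3, and 1.46, 1.75 and 1.32 FPKM with doxycycline. CCA1 stood at 15.1, 238 and 222 FPKM in controls 1 to 3 and 15.5, 14.6 and 12.2 FPKM with doxycycline, and RVE8 at 7.54, 166 and 116 against 6.44, 6.34 and 5.56 FPKM. Of genes that peak later in the day, PRR7 went the other way, at 126, 25.9 and 26.7 FPKM in controls and 99.5, 112 and 107 FPKM with doxycycline, while TOC1, at 19.9, 20.1 and 9.24 against 12.3, 14.6 and 14.6 FPKM, and ELF4, at 8.88, 9.97 and 2.85 against 9.69, 11.6 and 12.1 FPKM, were lower than in control 1 in control 3 but not in control 2. PRR5, at 15, 2.17 and 0.401 against 5.98, 7.75 and 8.51 FPKM, and GI, at 13.9, 10.5 and 3.63 against 6.44, 7.53 and 7.98 FPKM, were below control 1 in the doxycycline libraries too, as was TOC1. Among clock genes not looked at before, 10 of 10 morning-phased genes lay higher in control 2 than in control 1 and 5 of 8 day- and evening-phased genes lower, against 9 and 8 in control 3.

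Genes at least 2-fold below every control included runs of neighbours on the chromosomes. Among 18853 tested nuclear genes placed in the reference, 85 such genes formed 7 adjacent pairs, while 10000 random sets of 85 genes had a median of 0 pairs and at most 5. The longest run was 4 genes, against at most 3 in the random sets, and was made of UNE15 (AT4G13560), the histone gene HTA4 (AT4G13570), AT4G13572 and AT4G13575. HTA4 stood at 3.79, 7.64 and 2.86 FPKM in controls and 0.696, 0.439 and 0.187 FPKM with doxycycline, AT4G13575 at 27.0, 8.36 and 8.22 against 1.12, 1.95 and 2.14 FPKM, and UNE15 at 6.45, 6.86 and 3.29 against 0.159, 0.236 and 0.235 FPKM. The next genes outward among those tested were MIR397b (AT4G13555), at 7.07, 19.5 and 9.96 against 0.881, 3.49 and 3.05 FPKM, and AT4G13580, at 1.45, 4.91 and 9 against 4.02, 3.93 and 5.46 FPKM. Other adjacent pairs were the near-identical defensin genes PDF1.3 and PDF1.2b, VSP1 and VSP2, SOT18 and SOT16, and AT1G24145 and AT1G24147. The 33 placed genes at least 2-fold above every control formed 0 adjacent pairs. Whether the seedlings of the groups differ in DNA at the run of 4 genes was not tested, so its values, AT4G13572 among them, are not read as a response to doxycycline.

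Controls 2 and 3 stood apart from control 1 and from the doxycycline libraries. The design names no difference between the controls, so only differences in sampling, harvest and labels were tested. How RNA was selected was not tested as a source. Control 2 had the highest 18S ribosomal RNA value (10573 FPKM) and the highest summed mitochondrial (2215) and plastid (3677) FPKM of the 6 libraries. A larger share of root tissue cannot raise a gene by more than it raises root-specific genes. Yet 13.1% (control 2) and 4.99% (control 3) of genes at least 2-fold above control 1 lay farther above it than all 12 root markers. That argues against root tissue as the only cause. The root markers themselves lay above control 1 by a median of 1.46 log2 in control 2 and 1.62 in control 3. A larger share of root tissue as part of the cause thus stays open. Harvest at another time of day may account for part of the pattern: among the clock genes not looked at before, the 10 morning-phased exceeded the 8 day- and evening-phased ones, relative to control 1, by a difference in medians of 2.57 log2 in control 2 and 3.94 in control 3. Control 1 is not one more replicate of the doxycycline libraries under a wrong label: it lay at least 2-fold outside pairs of them in at least 539 genes, each doxycycline library outside the others in at most 67. A treated sample of another batch stays open, as the labels name no batches. Where control 1 lay at least 2-fold outside the 3 doxycycline libraries (441 genes), controls 2 and 3 lay on the same side in 226 and on the other in 61. All controls are compared here with the same doxycycline libraries, which by itself makes some agreement in side, so these counts do not decide it.

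A lower level of all genes does not account for the lower jasmonate genes with doxycycline: median-of-ratios scaling moved the median of all genes from -0.29 to -0.01 and that of the list only from -2.72 to -2.48. Controls 2 and 3 as the only source cannot be told apart from a response to doxycycline. Against control 1 the median of -1.11 lay at percentile 0 of matched random lists, and 18 of 20 genes lay below control 1 in all doxycycline libraries. However, random lists treat genes as independent, and control 1 is 1 library. With that 1 control and an estimated correlation the set test called no list of any kind, so it cannot decide. A smaller shift in harvest time between control 1 and the doxycycline libraries stays open, since the same clock genes differed by 0.79 log2, between the bounds set for presence and absence. A lower jasmonate response with doxycycline is a hypothesis that may be tested with controls harvested beside treated seedlings.

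In 14 of 16 mitochondrial dysfunction genes every doxycycline library lay above control 1, and in 0 all lay below it. A change of all genes of like abundance does not explain it, since the median of 0.77 lay at percentile 100 of the matched random lists, although these treat genes as independent and the adjusted p with an estimated correlation was 0.509. Low values in control 1 rather than a change with doxycycline cannot be told apart from a response to it, because the list's medians against controls 2 and 3 were -0.56 and -0.43, and these controls differ from control 1 in much else. The rise against control 1 was also not particular to mitochondrial stress. Root markers lay at percentile 99.66 of matched random lists, cell cycle genes at 99.69 and plastid genome genes at 100, while jasmonate genes lay at 0. A different share of tissues in control 1 was not tested, since the root test covered only controls 2 and 3. The response named by the series title may thus be present against control 1 and masked in controls 2 and 3, which these libraries do not decide.

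The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. Genes separated at least 2-fold numbered 121 for the real groups, a count that 1 split reached (the real one), and at most 2 in the other splits, each of which mixes the alike doxycycline libraries with controls, so that few genes can separate. The simulation with each group's own spread gave 47 without any change. Its spread was independent between genes, unlike that between these controls, so 47 is only a rough guide here. Shifted lists numbered 16 for the real groups, as many or more in 5 of the 10 splits, and up to 18 in another split. Changed genes numbered 0 in the real groups and at most 0 in the others, so all 10 splits tied, with or without the 2-fold minimum.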
